A study of Mus musculus with 8 samples.

How the data were processed

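The samples were 8 Agilent dual-colour arrays of cytoplasmic RNA from mouse bone marrow derived macrophages, 2 arrays in each of 4 groups, each with day 3 and day 0 RNA of 1 genotype and 1 experiment. The day 0 RNA of a genotype and experiment was used on both of its arrays. The authors scanned the arrays and ran Agilent Feature Extraction 10.7.3.1. Per the file headers, this program applied spatial and multiplicative detrending, replaced low signals by surrogates and normalized the dyes with LOWESS within each array. The deposited scanner files hold intensity values of each spot and its local background in both channels, before background subtraction, and processed intensity values. They also hold the deposited log10 ratio of red over green processed signal. The deposited value table holds the log10 ratio of day 3 over day 0, which equals that of the scanner files turned for the dye swap to within 5e-10. Other deposited columns hold flags of 0 or 1 for spots well above background, saturated spots and outliers. Between 25.7% and 30.8% of the spots of an array have a deposited log ratio of 0. Each array has 44397 spots, of which 43020 are not controls, for 39429 probes.

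Mean spot intensities were corrected for the local background median with normexp (offset 50), and log2 ratios were normalized by loess within each array with limma 3.58.1 in R 4.3.3. Files were read with data.table (version 1.17.8). Ratios were turned to day 3 over day 0. Spots marked as non-uniformity or population outliers were left out, and spots of 1 probe were averaged. Gene symbols come from the deposited annotation, updated through a RefSeq gene table (GRCm38.p6, names only) for 26412 probes and kept as deposited for the others, and positions are on the mm9 build of the array design. A probe was kept where it was well above background in both arrays of at least 1 group in the day 3 or the day 0 channel, which left 22406 probes. Each gene was represented by its probe with the highest mean intensity, giving 17997 genes, 78 of them with a missing value on at least 1 array.

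The limma model held 4 group means and a term for the experiment, which is also the dye direction and the slide; it has 3 residual degrees of freedom and 3.46 prior degrees of freedom. All tests are two-sided. The 9 comparisons were day 3 against day 0 in each group, the tamoxifen effect in each genotype, the difference of these effects, and the genotype effect with and without tamoxifen. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Deviations of the 2 replicates correlated between groups at 0.31 to 0.73. Named genes were fixed by a rule: Thoc5, and per comparison the 12 called genes with the largest change in each direction that moved the same way in both experiments; where 0 genes were called, those at an unadjusted p under 0.01 are given as values. A few genes that this rule or the list examples select are not reported here, but stay in each count. Where a group was not well above background, a fold is given as a bound or not at all.

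Gene lists, 31 in number for pathways and cell types, were fixed before the data were examined, with at least 5 measured genes each. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. This made 121 calls over the 9 comparisons, and 0 of them hold with an estimated correlation. As a further alternative the lists were tested with limma's fry, which does not set a list against the other genes. The lists reported are among those that passed with the preset correlation, and TREX and mRNA export in addition, with stromal genes for the genotypes with tamoxifen. Up to 4 genes per list, those with the smallest p, were taken as examples. Genes called at day 3 in 1 genotype were tested as sets in the tamoxifen effect of the other, so that no array served for both.

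Alternatives chosen before the data were examined were no term for the experiment, median centring in place of loess, Agilent's processed log ratios, the deposited value table, Aquantile or scale normalization between arrays, no filter or a strict filter on dim probes, the shared day 0 RNA as a random block (statmod 1.5.0), the mean of all probes of a gene, a fit of the compared arrays alone, the day 3 channel alone, a log2 fold change of at least 1, and each array left out in turn. The method was tested on simulated data drawn from the fitted means and variances, with 50 genes changed at each of several sizes in flox cells with tamoxifen. It called 18% of changes of 0.5, 96% of changes of 1 and 100% of changes of 2 in the tamoxifen effect, with 10 false calls among 167; in the difference of effects it called 0%, 70% and 98%, with 6 false among 140. The simulated errors were independent between arrays. In the data, arrays of 1 genotype and experiment share day 0 RNA, with a correlation of 0.325 in the random block fit. These rates may therefore not hold for the data. Median signal over background was 2.70 to 4.08 in the day 3 channel and 2.39 to 6.09 in the day 0 channel. Control spots were left out. The precision rests on 2 arrays per group; the median standard error was 0.127 for a tamoxifen effect and 0.18 for the difference of effects.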

Results

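Cytoplasmic RNA was measured on 8 dual-colour microarrays of mouse bone marrow derived macrophages. The cells came from control mice that carry a tamoxifen-inducible Cre recombinase (ERT2 Cre) and from mice in which that Cre can remove both floxed copies of Thoc5. Thoc5 encodes a subunit of the TREX complex, which takes part in mRNA export from the nucleus. Each array set RNA from day 3 under CSF-1, the growth factor that drives macrophage differentiation, against day 0 RNA of the same genotype and experiment. The 4 groups, control and flox cells without and with tamoxifen, held 2 arrays each, 1 from each of 2 biological experiments. Experiment 2 used the opposite dyes, so experiment, slide and dye direction are the same split. Between 51.2% and 57.9% of probes were well above background per channel, and 0 spots were saturated. The 2 arrays of a group correlated across 17997 genes at r = 0.78 for control cells without tamoxifen, 0.88 for control cells with tamoxifen, 0.93 for flox cells without and 0.92 for flox cells with tamoxifen. Genes are not independent replicates, and 2 arrays per group limit the precision of every value below. Changes are on the log2 scale with the standard error of the limma fit and n = 2 arrays per group, and adjusted p is the Benjamini-Hochberg value over the 17997 genes.

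The first question was whether tamoxifen removed Thoc5 RNA. The Thoc5 probe lies on chromosome 11 at 4828807 to 4828866 of the mm9 build. In flox cells with tamoxifen, Thoc5 was 8.16-fold lower at day 3 than at day 0, with log2 ratios of -3.04 and -3.02 on the 2 arrays. In flox cells without tamoxifen the ratios were -0.74 and -0.77, in control cells without tamoxifen -0.40 and -0.28, and in control cells with tamoxifen -0.21 and -0.15. Tamoxifen lowered Thoc5 in flox cells 4.83-fold (log2 change -2.27 ± 0.10, 95% interval -2.51 to -2.04, limma adjusted p = 0.000709, and 9.59e-17 to 0.013 over its alternatives). In control cells the change was 0.16 ± 0.10 (limma adjusted p = 1), and the difference between the genotypes was -2.43 ± 0.14 (limma adjusted p = 0.00901). That difference stayed between -2.48 and -2.38 when single arrays were left out, but missed the threshold without the first or second array of control cells with tamoxifen (limma adjusted p = 0.115 and 0.128), the first or second of flox cells without tamoxifen (0.062 and 0.0559) or the second of flox cells with tamoxifen (0.0696). Without tamoxifen the Thoc5 ratio of flox cells differed from that of control cells by -0.42 ± 0.10, which did not pass the test (limma adjusted p = 0.073). Over the alternatives to this ratio comparison, limma adjusted p ranged from 0.0406 to 0.519. Of them only the day 3 channel alone passed, where Thoc5 of flox cells differed by -0.56 (limma adjusted p = 0.0406).

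**Figure D1:**
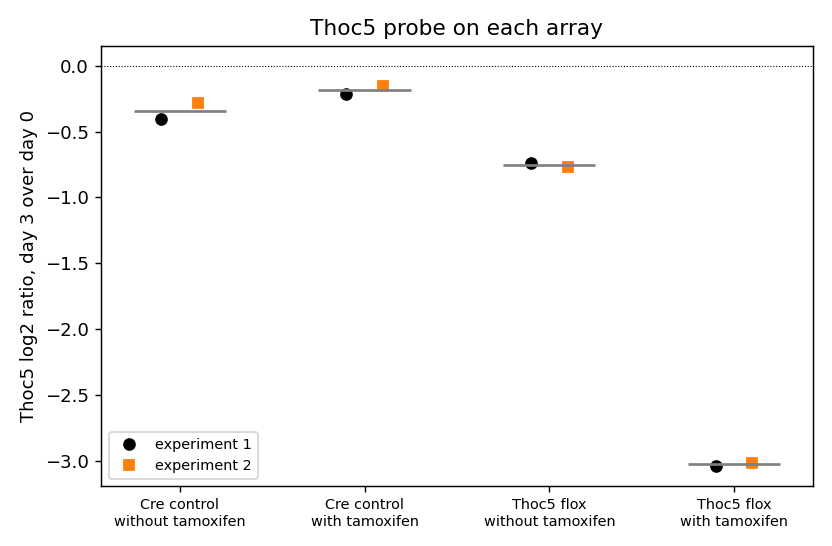
Each point is the log2 ratio of day 3 over day 0 for the Thoc5 probe on 1 array, by group; circles are experiment 1, squares experiment 2, and the grey line is the mean of the 2 arrays. The arrays of flox cells with tamoxifen sit at -3.04 and -3.02, and those of the other groups between -0.77 and -0.15.

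Day 3 against day 0 in control cells without tamoxifen describes the change of the culture under CSF-1, called differentiation here. A loss of other cell types and a change within cells cannot be told apart in it. RNA of genes of neutrophils and their precursors was among that which fell most. The antimicrobial peptide gene Camp was 70.2-fold lower (-6.13 ± 0.08), S100a8 61.7-fold lower (-5.95 ± 0.09) and S100a9 44.4-fold lower (-5.47 ± 0.07). The protease gene Ctsg was 28.2-fold lower (-4.82 ± 0.07) and Mpo, the myeloperoxidase gene, 11.2-fold lower (-3.48 ± 0.07). Of 29 measured genes of the neutrophil list, 28 were lower, 0 were higher and 1 did not pass, with a median of -2.60 (28 lower adjusted over the list alone; adjusted p = 0.276 with an estimated correlation). The complement regulator Cd55 was 11.2-fold higher (3.49 ± 0.18), ceruloplasmin (Cp) 10.9-fold higher (3.45 ± 0.11), the chemokine gene Ccl8 9.61-fold higher (3.26 ± 0.13) and apolipoprotein E (Apoe) 8.36-fold higher (3.06 ± 0.18). Tmem176a, Cd55b, Raver2, Nrxn2, Enpp2, Fgl2, Cd5l and Pgbd5 rose by 3.01 to 3.47. Further probes stood at 0.25 for Cd55b, 1.35 for Cp and 1.17 for Nrxn2. The other lower genes named were Chil3, Wfdc21, Ms4a3, Retnlg, Ltf, Cstdc5 and Mmp8, from -5.73 to -3.32.

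Cell division genes fell with differentiation in these control cells. All 36 measured genes of the G2 and mitosis list were lower (median -1.60; 36 adjusted over the list alone), among them Mki67 (-2.69 ± 0.10), the mitotic kinase gene Plk1 (-1.64 ± 0.07) and the cyclin gene Ccna2 (-2.31 ± 0.10); adjusted p = 0.39 with an estimated correlation. Of 40 S phase genes, 34 were lower, 2 higher and 4 did not pass (35 lower and 2 higher adjusted over the list alone), such as the replication helicase gene Mcm2 at -2.27 ± 0.11; adjusted p = 0.551 with an estimated correlation. All 14 megakaryocyte and platelet genes were lower (median -1.70; 14 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation). Of 22 stem and progenitor genes, 15 were lower, 1 higher and 6 did not pass (15 lower and 1 higher adjusted over the list alone; adjusted p = 0.39 with an estimated correlation). Cd34 stood at -3.20 ± 0.11 and Myb at -2.95 ± 0.12. Of 29 hypoxia and glycolysis genes, 20 were lower, 1 higher and 8 did not pass (21 lower and 1 higher adjusted over the list alone; adjusted p = 0.545 with an estimated correlation).

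Of 24 cholesterol synthesis genes, 16 were higher in the same comparison, 1 lower and 7 did not pass (16 higher and 1 lower adjusted over the list alone; adjusted p = 0.357 with an estimated correlation). Insig1 stood at 1.42 ± 0.07. Of 22 genes of the LXR and lipid handling list, 12 were higher, 5 lower and 5 did not pass (12 higher and 5 lower adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). The cholesterol exporter gene Abca1 stood at 2.03 ± 0.14. Of 30 macrophage markers, 14 were higher, 8 lower and 8 did not pass (14 higher and 8 lower adjusted over the list alone; adjusted p = 0.357 with an estimated correlation); the complement genes C1qa and C1qb stood at 1.67 ± 0.08 and 1.81 ± 0.10. Of 28 monocyte and macrophage transcription factors, 16 were higher, 4 lower and 8 did not pass (16 higher and 4 lower adjusted over the list alone; adjusted p = 0.356 with an estimated correlation), with Spi1, which encodes PU.1, at 2.24 ± 0.19. Of 17 monocyte genes, 11 were lower, 2 higher and 4 did not pass (12 lower and 2 higher adjusted over the list alone; adjusted p = 0.356 with an estimated correlation). The chemokine receptor gene Ccr2 stood at -2.51 ± 0.10. Of 13 MHC class II genes, 7 were higher, 2 lower and 4 did not pass (7 higher and 3 lower adjusted over the list alone; adjusted p = 0.673 with an estimated correlation). Of 26 measured genes of TREX and mRNA export, 14 were lower, 2 higher and 10 did not pass (14 lower and 2 higher adjusted over the list alone; adjusted p = 0.581 with an estimated correlation). Alyref stood at -1.34 ± 0.08 and the THO subunit gene Thoc3 at 0.69 ± 0.12. In all, limma called 10325 of 17997 genes at adjusted p under 0.05, 4189 higher and 6136 lower, and 1889 of them changed at least 2-fold. Of 2210 called genes with a further probe, 715 had a further probe of opposite sign, 403 of them at an unadjusted p under 0.05, so each value holds for the probe measured.

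The same comparison in the other groups gave 10379 called genes in control cells with tamoxifen (4300 higher, 6079 lower), 10300 in flox cells without tamoxifen (4293 higher, 6007 lower) and 10602 in flox cells with tamoxifen (4590 higher, 6012 lower). Without the first or second array of the group these counts were 5700 and 5475, 5894 and 6147, and 5899 and 7457 in that order. Camp changed by -5.82 ± 0.08 in control cells with tamoxifen, by -6.66 ± 0.08 in flox cells without it and by -6.79 ± 0.08 in flox cells with it. Chil3, S100a8, S100a9, Ctsg, Ms4a3 and Cstdc5 were also among the 12 most lowered genes of each group. In flox cells with tamoxifen, 27 of 29 neutrophil genes were lower, 1 higher and 1 did not pass (median -3.24; 28 lower and 1 higher adjusted over the list alone; adjusted p = 0.251 with an estimated correlation). There, 35 of 36 G2 and mitosis genes were lower and 1 did not pass (median -1.18; 35 lower adjusted over the list alone; adjusted p = 0.441 with an estimated correlation). Of 39 lysosome genes, 20 were higher, 4 lower and 15 did not pass in flox cells with tamoxifen (20 higher and 4 lower adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), and 17 of 30 macrophage markers were higher, 9 lower and 4 did not pass (17 higher and 9 lower adjusted over the list alone; adjusted p = 0.289 with an estimated correlation). The most raised genes of that group included H2-M2 (3.54 ± 0.11), the proton pump subunit gene Atp6v0d2 (3.44 ± 0.17), Cd83 (2.61 ± 0.11) and the transcription factor gene Egr2 (2.40 ± 0.11).

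Most of the differentiation response was shared by flox cells with tamoxifen. Of the 4189 genes higher at day 3 in control cells without tamoxifen, 2758 were also called higher in flox cells with tamoxifen, or 65.8%, where independent lists would share 1068, and 242 were called lower. Of the 6136 genes lower, 4308, or 70.2%, were called lower in both, where independent lists would share 2050, and 232 were called higher. The log2 ratios of these 2 groups correlated across genes, which are not independent replicates, at r = 0.74, against r = 0.87 between control and flox cells both without tamoxifen. Tamoxifen moved the 4189 genes raised in control cells by a median of -0.045 in flox cells, 174 called higher and 363 called lower (limma camera adjusted p = 0.0146; adjusted p = 0.582 with an estimated correlation, and 0.00057 to 0.582 over its alternatives). The 6136 lowered genes moved by a median of 0.011, with -0.033 and 0.058 in the experiments, 391 called higher and 183 called lower (limma camera adjusted p = 0.218; adjusted p = 0.628 with an estimated correlation, and 0.0459 to 0.628 over its alternatives). In control cells, tamoxifen moved the 4293 genes raised in flox cells without tamoxifen by a median of 0.054, upward by the test (limma camera adjusted p = 0.00714), and the 6007 lowered genes by -0.019, downward (limma camera adjusted p = 0.0146). Both have adjusted p = 0.582 with an estimated correlation. With arrays centred on their medians, the median of the lowered genes in control cells was 0.05 while the test still pointed down.

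The tamoxifen effect in flox cells describes what loss of Thoc5 RNA goes with at day 3, together with any action of the drug itself. Only cytoplasmic RNA was measured, so less RNA in the whole cell and less RNA exported to the cytoplasm cannot be told apart. Among the genes raised most, the endolysosomal channel gene Mcoln3 was 12.6-fold higher with tamoxifen (3.66 ± 0.17, limma adjusted p = 0.000709), Cd83 7.63-fold higher (2.93 ± 0.16), Atp6v0d2 6.00-fold higher (2.59 ± 0.24), Egr2 5.38-fold higher (2.43 ± 0.16) and the fatty acid binding protein gene Fabp4 5.23-fold higher (2.39 ± 0.21). H2-M2, Gpr162, Pianp, Il7r, Oit3, Fam20c and Mmp12, the macrophage elastase gene, rose by 2.34 to 3.22. Among those lowered, the chemokine gene Ccl12 was 7.81-fold lower (-2.97 ± 0.38) and the cytokine receptor gene Il2ra at least 4.09-fold lower. Id1, an inhibitor of DNA binding by other transcription factors, was 11.4-fold lower (-3.51 ± 0.63, limma adjusted p = 0.0237), Smad6, which encodes an inhibitory SMAD, 4.95-fold lower (-2.31 ± 0.39), and Raver2 6.49-fold lower (-2.70 ± 0.14). Nrxn2, Cd209f, Ch25h, Dmwd and Klra2 stood between -2.78 and -2.20. Of the 24 genes with the largest changes 15 to 19 passed without 1 array of flox cells, and Gpr162, Il7r, Oit3, Mmp12, Id1, Ccl12, Ch25h, Smad6 and Dmwd each missed the threshold in at least 1 of these fits, Id1 with limma adjusted p up to 0.138 in these and up to 0.378 over its alternatives, the highest without a term for the experiment. With 1 array of flox cells left out Id1 ranged from -4.34 to -2.68, Gpr162 from 2.34 to 3.54 and Mmp12 from 1.52 to 3.17. Further probes stood at 2.15 for Mcoln3, 1.05 for Mmp12 and -0.94 for Nrxn2.

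In flox cells under tamoxifen, 18 of 39 lysosome genes were higher, 1 lower and 20 did not pass, with a median of 0.51 and medians of 0.48 and 0.51 in the experiments (22 higher and 1 lower adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). The protease genes Ctsb (1.06 ± 0.10), Ctsd (1.08 ± 0.12) and Ctsk (2.05 ± 0.22) were higher. Of 30 macrophage markers 8 were higher, 4 lower and 18 did not pass (13 higher and 4 lower adjusted over the list alone; adjusted p = 0.405 with an estimated correlation). Gpnmb stood at 1.71 ± 0.17 and the Fc receptor gene Fcgr1 at -0.86 ± 0.11. Of 17 monocyte genes 6 were lower, 0 higher and 11 did not pass (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.388 with an estimated correlation). Ccr2 stood at -1.64 ± 0.14 and F13a1 at -1.70 ± 0.15. Of 24 cholesterol synthesis genes 6 were lower, 1 higher and 17 did not pass (11 lower and 1 higher adjusted over the list alone; adjusted p = 0.405 with an estimated correlation). Sqle stood at -1.07 ± 0.11 and Idi1 at -0.95 ± 0.10. Of 29 ribosome biogenesis and MYC target genes 5 were lower, 0 higher and 24 did not pass (median -0.50; 18 lower adjusted over the list alone; adjusted p = 0.789 with an estimated correlation). Srm stood at -0.80 ± 0.14. Of 36 G2 and mitosis genes 8 were lower, 0 higher and 28 did not pass (median -0.26; 11 lower adjusted over the list alone; adjusted p = 0.792 with an estimated correlation). Ube2c stood at -1.14 ± 0.10. Of 38 interferon-stimulated genes 4 were lower, 0 higher and 34 did not pass (8 lower adjusted over the list alone; adjusted p = 0.792 with an estimated correlation). Isg15 stood at -0.82 ± 0.15. Of 40 S phase genes 4 were higher, 0 lower and 36 did not pass (4 higher adjusted over the list alone; adjusted p = 0.852 with an estimated correlation); the median of 0.19 became -0.04 without the array of flox cells without tamoxifen from experiment 2. Of 26 genes of TREX and mRNA export other than Thoc5, 0 passed (median -0.09; 0 adjusted over the list alone; adjusted p = 0.852 with an estimated correlation), and those with the smallest p were Thoc1 at -0.33 ± 0.11, Ddx39b at 0.39 ± 0.13, Nxt1 at -0.42 ± 0.19 and Ddx19a at -0.21 ± 0.11.

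In all, limma called 1624 genes for tamoxifen in flox cells, 876 higher and 748 lower, of which 475 changed at least 2-fold (240 higher, 235 lower), and 1624 of 1624 had the same sign in both experiments. The count was 470 without a term for the experiment, 2905 with the shared day 0 RNA as a random block and 4584 in a fit of the 4 flox arrays alone. It was 311 and 224 without the first or second array of flox cells without tamoxifen and 456 and 232 without the first or second array of those with tamoxifen. Of 381 called genes with a further probe, 27 had a further probe of opposite sign.

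The tamoxifen effect in control cells measures the drug and the activated Cre without a floxed gene. No gene passed the limma test (0 of 17997, smallest adjusted p = 0.161), while 994 genes had an unadjusted p under 0.05, where chance would give 900. The latter count was 1981 and 1491 without the first or second array of control cells without tamoxifen, and 941 and 454 without the first or second of those with tamoxifen. It was 457 without a term for the experiment and 1528 with the shared day 0 RNA as a random block. The genes with the largest values at an unadjusted p under 0.01 included Vegfa, the vascular growth factor gene (-1.73 ± 0.17, adjusted p = 0.161), Tgm2 (-1.46 ± 0.15, adjusted p = 0.161), Thbs1 (-2.10 ± 0.40, adjusted p = 0.452), the stress-response gene Chac1 (1.90 ± 0.40, adjusted p = 0.46) and the p53 target gene Gdf15 (0.86 ± 0.15, adjusted p = 0.404). With 1 array left out Thbs1 ranged from -2.75 to -1.45 and Chac1 from 1.23 to 2.57. Mitosis genes were among the higher values, with Cdkn3 at 0.96 ± 0.14, Ube2c at 0.89 ± 0.10 and Ccnb2 at 0.88 ± 0.13. In the G2 and mitosis list 0 of 36 genes passed over all genes and 33 were higher adjusted over the list alone; its median was 0.58, with 0.52 and 0.63 in the experiments (adjusted p = 0.29 with an estimated correlation). The interferon-stimulated list had a median of -0.30 with 0 of 38 genes passing (0 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation), and the inflammatory cytokine list a median of -0.19 with 0 of 33 passing (0 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation). The p53 target list had a median of 0.13 with 0 of 27 passing (2 higher adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), and the S phase list 0.20 with 0 of 40 passing (0 adjusted over the list alone; adjusted p = 0.683 with an estimated correlation). The S phase median became 0.05 with a test downward without the first array of control cells without tamoxifen. Centring arrays on their medians instead of loess gave 27 called genes.

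**Figure D2:**
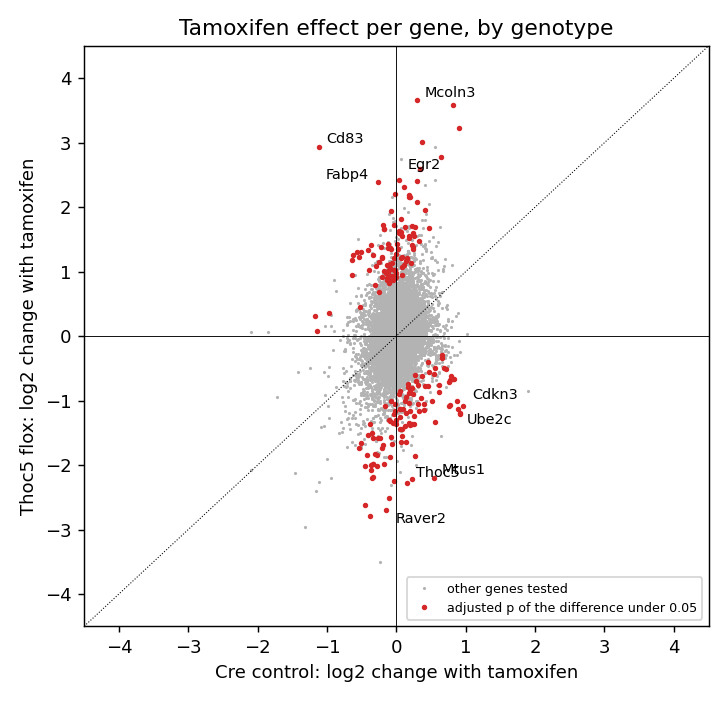
Each point is 1 of 17997 genes, with the log2 change under tamoxifen in control cells on the x axis and in flox cells on the y axis; red points are the 205 genes whose effects differed between the genotypes, and the dotted line marks equal effects. Thoc5 lies at 0.16 and -2.27, and Cd83 at -1.11 and 2.93.

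The difference of the tamoxifen effects between flox and control cells takes out what the drug and the Cre do alike in both genotypes. A difference between the genotypes without tamoxifen enters it with opposite sign, so it does not isolate the floxed gene. In the day 3 channel alone, flox minus control was -2.47 for Cd83 without tamoxifen and 1.66 with it. For Cdkn3 it was 1.38 and -0.72, and for Mcoln3 -0.13 and 3.13. Cd83 differed most (4.04 ± 0.22, limma adjusted p = 0.00901), with 2.93 in flox and -1.11 in control cells, followed upward by Mcoln3 (3.35 ± 0.23), Fabp4 (2.65 ± 0.30), Egr2 (2.39 ± 0.22), Atp6v0d2 (2.24 ± 0.33) and the deiodinase gene Dio2 (2.23 ± 0.30). Pianp, Fam20c, Mctp1 and the beta-glucan receptor gene Clec7a differed by 2.00 to 2.14, but a further probe of Mctp1 stood at 0.14 (unadjusted p = 0.565). H2-M2 was also called, but is not well above background in some of the groups, so no fold is given. Downward stood Mtus1 (-2.74 ± 0.32), Raver2 (-2.55 ± 0.20), Dmwd (-2.45 ± 0.34), Thoc5, Nrxn2 (-2.41 ± 0.37), Cd209f (-2.40 ± 0.22) and Fut7 (-2.13 ± 0.18). The mitosis genes Cdkn3 (-2.05 ± 0.19), Ube2c (-2.02 ± 0.15), Ccnb2 (-1.89 ± 0.18) and the cell polarity gene Sapcd2 (-2.10 ± 0.14) were lower by this difference, as was Rab32 (-1.88 ± 0.22). Further probes of Mcoln3 and Nrxn2 stood at 2.05 and -0.61, and 22 of the 24 genes with the largest differences passed with the mean over all probes of a gene. Of these 24 genes 0 passed without either array of control cells with tamoxifen, either array of flox cells without tamoxifen or the second array of flox cells with tamoxifen, 13 passed without the first array of flox cells with tamoxifen, and 22 and 19 without the first or second array of control cells without tamoxifen.

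Of the 36 G2 and mitosis genes 9 differed downward, 0 upward and 27 did not pass, with a median of -0.78 and -0.85 and -0.80 in the experiments (27 lower adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Of 39 lysosome genes 3 differed upward, 0 downward and 36 did not pass, with a median of 0.54 (17 higher adjusted over the list alone; adjusted p = 0.0856 with an estimated correlation). Ctsb stood at 1.15 ± 0.15 and Atp6v1a at 1.12 ± 0.17. Of 22 LXR and lipid handling genes 2 differed upward, 1 downward and 19 did not pass (10 higher and 2 lower adjusted over the list alone; adjusted p = 0.336 with an estimated correlation); Pparg, which encodes a lipid-sensing nuclear receptor, stood at 1.01 ± 0.14 and Acp5 at -1.52 ± 0.19. Of 30 macrophage markers 3 differed upward, 1 downward and 26 did not pass (7 higher and 4 lower adjusted over the list alone; adjusted p = 0.429 with an estimated correlation). Gpnmb stood at 1.48 ± 0.23 and the scavenger receptor gene Marco at -1.52 ± 0.21. Of 17 monocyte genes 1, Treml4 at -1.52 ± 0.22, differed downward, 0 upward and 16 did not pass (5 lower adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Of 24 cholesterol synthesis genes 0 passed over all genes (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.472 with an estimated correlation). Sqle stood at -0.95 ± 0.16. In all, limma called 205 genes, 98 upward and the others downward. The count was 22 without a term for the experiment, 59 with Agilent's processed log ratios, 378 with median centring and 824 with the shared day 0 RNA as a random block. It fell to 0 without either array of control cells with tamoxifen, either array of flox cells without tamoxifen or the second array of flox cells with tamoxifen, and to 24 without the first array of flox cells with tamoxifen; it was 284 and 139 without the first or second array of control cells without tamoxifen. Of 52 called genes with a further probe, 6 had a further probe of opposite sign.

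**Figure D3:**
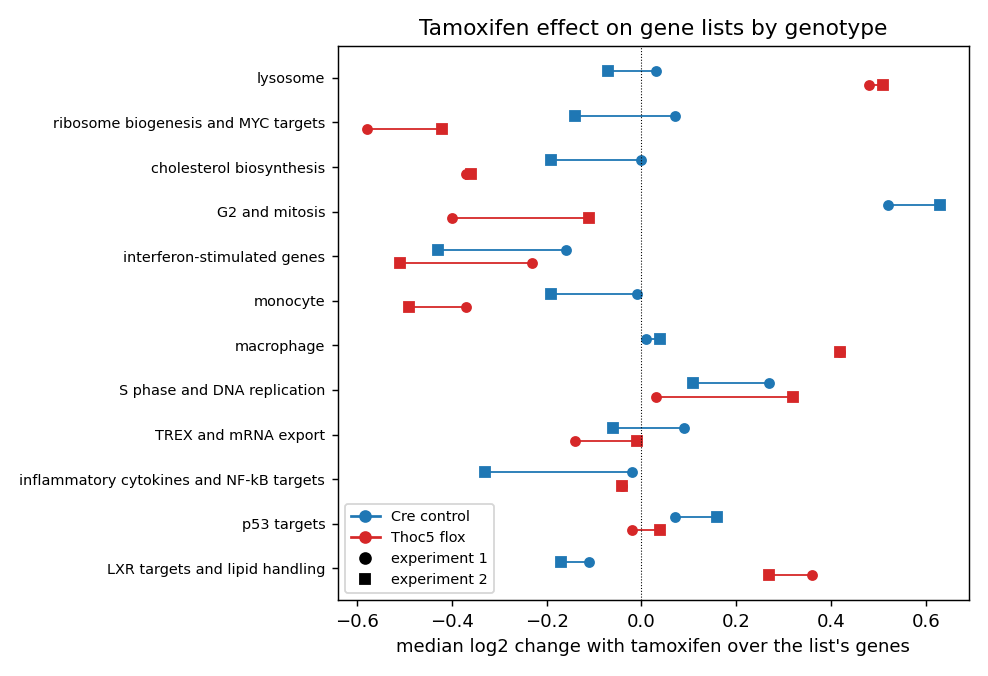
Each pair of joined points gives the median log2 change under tamoxifen over the genes of a list, circles for experiment 1 and squares for experiment 2, blue for control and red for flox cells. The G2 and mitosis medians are 0.52 and 0.63 in control cells and -0.40 and -0.11 in flox cells, and the lysosome medians 0.03 and -0.07 in control cells and 0.48 and 0.51 in flox cells.

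Flox and control cells were also compared directly at the same treatment, each by its ratio to its own day 0. With tamoxifen, Id1 was 30.9-fold lower in flox cells (-4.95 ± 0.63, limma adjusted p = 0.00979), Ccl8 10.2-fold lower (-3.36 ± 0.18), Smad6 7.37-fold lower (-2.88 ± 0.39), Thoc5 7.20-fold lower (-2.85 ± 0.10), Ccl12 6.67-fold lower (-2.74 ± 0.38) and Id3, a relative of Id1, 5.29-fold lower (-2.40 ± 0.42). In the day 0 channel Id1 was higher in flox cells by 1.27 (0.49 and 2.06 in the experiments), Id3 by 0.52 (-0.29 and 1.34) and Smad6 by 0.46 (-0.26 and 1.18). In the day 3 channel alone Id1 stood at -3.67, Id3 at -2.05 and Smad6 at -2.45. Nrxn2, Nrg1, Raver2, Dnah2 and Dmwd stood between -2.81 and -2.44. Mcoln3 was 5.86-fold higher (2.55 ± 0.17; 3.13 in the day 3 channel alone), the C-type lectin receptor gene Clec4e 4.40-fold higher (2.14 ± 0.15), and Oit3, Il7r, Rasgef1a, Anxa1, Slc9b2, Mctp1, Plk2 and the chemokine gene Cxcl1 were higher by 1.88 to 2.35. Further probes of Mctp1 and Nrxn2 stood at 0.28 and -1.02. H2-M2, Sox7 and Camkk1 were called but are not well above background in some of the groups, so no fold is given. Of the 26 TREX and mRNA export genes other than Thoc5, 1 was higher, 0 lower and 25 did not pass (0 adjusted over the list alone; adjusted p = 0.783 with an estimated correlation): the RNA helicase gene Ddx39b at 0.57 ± 0.13 (limma adjusted p = 0.0371). Of the 24 genes with the largest changes 0 and 8 passed without the first or second array of control cells with tamoxifen, and 17 and 14 without the first or second array of flox cells with tamoxifen; Thoc5 had limma adjusted p = 0.0536 without the first array of control cells with tamoxifen.

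With tamoxifen, 15 of 40 S phase genes were higher in flox cells, 0 lower and 25 did not pass (27 higher adjusted over the list alone; adjusted p = 0.555 with an estimated correlation). Rrm2 stood at 1.32 ± 0.19. The S phase difference was not larger than without tamoxifen: by the ratio its median was 0.56 with tamoxifen and 0.66 without it. In the day 3 channel alone the S phase median was 0.83, against 0.82 without tamoxifen. That of 24 stromal, fibroblast and endothelial genes, chosen after their values were seen, was also 0.83 there, with 0.24 and 1.71 in the experiments, 11 called higher and 0 lower. By the ratio their median was 0.29, with -0.25 and 1.25 in the experiments, and 1 was higher, 2 lower and 21 did not pass (4 higher and 2 lower adjusted over the list alone; adjusted p = 0.783 with an estimated correlation). Of 39 lysosome genes 12 were higher, 1 lower and 26 did not pass (14 higher and 1 lower adjusted over the list alone; adjusted p = 0.298 with an estimated correlation). The protease gene Ctsb stood at 0.86 ± 0.10. Of 24 cholesterol synthesis genes 9 were lower, 1 higher and 14 did not pass (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.407 with an estimated correlation). Cyp51 stood at -0.80 ± 0.10. Of 17 monocyte genes 8 were lower, 0 higher and 9 did not pass (11 lower and 2 higher adjusted over the list alone; adjusted p = 0.298 with an estimated correlation). F13a1 stood at -2.20 ± 0.15. Of 29 neutrophil genes 14 had a lower ratio, 1 a higher one and 14 did not pass (17 lower and 2 higher adjusted over the list alone; adjusted p = 0.298 with an estimated correlation). Ms4a3 stood at -1.20 ± 0.12. The day 0 RNA of flox cells held more of these genes: in the day 0 channel 11 of 29 were called higher and 0 lower, 27 had values above 0 and the median was 0.97, and in the day 3 channel alone the median difference was 0.63. Of 14 megakaryocyte and platelet genes 7 had a lower ratio, 1 a higher one and 6 did not pass (11 lower and 1 higher adjusted over the list alone; adjusted p = 0.542 with an estimated correlation), while the list's day 0 median was 0.70 higher in flox cells and its day 3 difference was -0.07. In all, limma called 2026 genes with tamoxifen, 975 higher and 1051 lower in flox cells. The count was 531 without a term for the experiment, 1239 with Agilent's processed log ratios and 3140 in the day 3 channel alone. It was 0 and 26 without the first or second array of control cells with tamoxifen, and 326 and 258 without the first or second array of flox cells with tamoxifen. Of 469 called genes with a further probe, 52 had a further probe of opposite sign.

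Without tamoxifen, the 2 genotypes already differed. The stress-response gene Chac1 was 6.71-fold higher in flox cells (2.75 ± 0.40, limma adjusted p = 0.0377), Gpr84 3.35-fold higher (1.75 ± 0.20), and the replication and division genes Dtl (1.69 ± 0.23), Hells (1.68 ± 0.27), Cdkn3 (1.49 ± 0.14), Timeless (1.41 ± 0.15), Ndc80 (1.37 ± 0.22) and Exo1 (1.36 ± 0.20) were higher. Uchl1, Fignl1, Ddias and Cenpq were higher by at least 1.34. Ccl8 was 6.87-fold lower (-2.78 ± 0.18, limma adjusted p = 0.0173), Thbs1 6.58-fold lower (-2.72 ± 0.40), Cd83 4.92-fold lower (-2.30 ± 0.16), the growth factor gene Nrg1 4.67-fold lower (-2.22 ± 0.18) and the corepressor gene Bcor 4.47-fold lower (-2.16 ± 0.17). Ednrb, H2-Q8, Plac8 and Clec7a stood between -1.70 and -1.45. Clec4f, Stfa1 and Cstdc6 had lower ratios in flox cells, but some groups are not well above background, and their day 0 values in flox cells were higher by 2.58, 2.58 and 2.04; the day 0 value of Plac8 was higher by 1.11. With 1 array left out Chac1 ranged from 2.07 to 3.42. Of these 24 genes 0 passed without either array of flox cells, 11 and 6 without the first or second array of control cells, 1 without a term for the experiment and 1 with Agilent's processed log ratios.

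Of 36 G2 and mitosis genes 25 were higher in flox cells without tamoxifen, 0 lower and 11 did not pass (median 0.82; 34 higher adjusted over the list alone; adjusted p = 0.247 with an estimated correlation). Ube2c stood at 1.29 ± 0.10 and Nusap1 at 1.21 ± 0.13. Of 40 S phase genes 9 were higher, 0 lower and 31 did not pass (24 higher adjusted over the list alone; adjusted p = 0.37 with an estimated correlation). Mcm10 stood at 1.22 ± 0.11. Of 29 genes of the unfolded protein and integrated stress responses 3 were higher, 0 lower and 26 did not pass (12 higher and 1 lower adjusted over the list alone; adjusted p = 0.283 with an estimated correlation): Chac1, the asparagine synthetase gene Asns (1.18 ± 0.20) and the serine synthesis gene Psat1 (1.30 ± 0.17). Of 22 LXR and lipid handling genes 4 were lower, 0 higher and 18 did not pass (11 lower adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). Abca1 stood at -1.34 ± 0.20. Of 28 monocyte and macrophage transcription factors 6 were lower, 0 higher and 22 did not pass (9 lower adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). Irf5 stood at -1.04 ± 0.12 and Egr2 at -1.16 ± 0.16. Of 39 lysosome genes 1, Tpp1 at -0.64 ± 0.12, was lower, 0 higher and 38 did not pass (3 lower adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). Of 29 neutrophil genes 9 had a lower ratio, 0 a higher one and 20 did not pass (14 lower adjusted over the list alone; adjusted p = 0.161 with an estimated correlation), while their median was 0.97 higher in flox cells at day 0 and 0.42 higher in the day 3 channel alone. In all, limma called 517 genes without tamoxifen, 259 higher and 258 lower in flox cells. The count was 2 without a term for the experiment, 5 with Agilent's processed log ratios, 0 in a fit of the 4 arrays compared and 1801 in the day 3 channel alone. It was 156 and 12 without the first or second array of control cells, and 0 without either array of flox cells. Of 108 called genes with a further probe, 6 had a further probe of opposite sign.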

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

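Chosen only after the result was seen were the tests on cell types, on the control arrays without tamoxifen and on granulocyte genes. Everything in this part was brought up by a difference between the genotypes: a test of the difference of the tamoxifen effects called 205 genes.

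By the genes called, the tamoxifen response was larger in flox cells (1624 genes) than in control cells (0 genes). By the lists called with the preset correlation it was not: 14 of 31 lists passed in control cells and 10 in flox cells. In each genotype 0 of them held with an estimated correlation. If tamoxifen acted alike in both genotypes, the genes called in flox cells would move alike in control cells, but their median there, signed by the flox direction, was 0.07 against 0.77 in flox cells. A lower share of macrophages would raise the other cell type lists together, which was not seen. Of these 11 lists, 7 had medians below 0, and the highest median was 0.5. The lowest was -0.44 for monocyte genes, with 6 of 17 lower, 0 higher and 11 that did not pass (8 lower and 1 higher adjusted over the list alone). The monocyte list had limma camera adjusted p = 0.388 with an estimated correlation. That test cannot decide, since no list call held with it in any comparison. A lower share of macrophages therefore cannot be told apart. Loss of Thoc5 may explain the response as a hypothesis, while a change of cell types stays open, as do, untested, an action of Cre on the floxed locus itself, other differences between the mice and the timing of tamoxifen, which is not given in the sources used here. Whether RNA changed in the whole cell or in the cytoplasm alone was not measured.

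The median of the G2 and mitosis list was 0.58 in control cells under tamoxifen, where 0 of 36 genes passed (33 higher adjusted over the list alone; adjusted p = 0.29 with an estimated correlation), and -0.26 in flox cells (adjusted p = 0.792 with an estimated correlation). The difference had a median of -0.78, with 9 of 36 genes lower, 0 higher and 27 that did not pass (27 lower adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). The loess step within arrays does not account for it, since median centring in its place gave -0.80 relative to the median of all genes. Low values in the control arrays without tamoxifen alone would leave the flox effect unchanged, since it does not use these arrays. There 8 members were called lower and 0 higher, where the share over all genes would give 1.5 lower. Mitosis genes move together, so these calls are not independent. The list test with an estimated correlation cannot decide, since no list call held with it in any comparison. Such low values therefore cannot be told apart. The list's genotype difference was 0.82 without tamoxifen and -0.02 with it (adjusted p = 0.247 and 0.831 with an estimated correlation). This pair restates the difference of the effects. It cannot tell low values in control cells from high values in flox cells without tamoxifen. A difference in growth between the genotypes stays open and was not tested.

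The genotypes differed without tamoxifen, where 517 genes were called. A difference of the day 0 RNA would leave little in the day 3 channel. The called genes had a median signed difference of 0.79 there, against 0.85 for the ratio. They were picked and signed by ratios that hold the same day 3 values, so this median cannot exclude a day 0 source. The day 3 channel alone, tested over all genes, called 1801. For the granulocyte genes a day 0 difference may be the source: their median at day 0 was higher in flox cells by 1.06 and 0.79 in the experiments, with 11 of 29 called higher and 0 lower. Their day 3 difference of 0.42 was upward while their ratio difference was -0.26. Partial loss of Thoc5 without tamoxifen cannot be told apart. The Thoc5 ratio differed by -0.42 (limma adjusted p = 0.073, and 0.0406 to 0.519 over its alternatives). Of these only the day 3 channel alone passed, with -0.56 (limma adjusted p = 0.0406). The signed median of 500 genes picked in 1 experiment was -0.13 and 0.01 in the other, mean -0.06. It cannot decide, since any other deviation of flox cells without tamoxifen enters the sign and the difference oppositely and pushes this median down. Genetic background, which the labels give as mixed, and the experiment stay open, and the 517 calls fell to 0 without either array of flox cells.

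By the difference of the tamoxifen effects, 3 of 39 lysosome genes were higher, 0 lower and 36 did not pass (median 0.54; 17 higher adjusted over the list alone; adjusted p = 0.0856 with an estimated correlation). Of 30 macrophage markers 3 were higher, 1 lower and 26 did not pass (median 0.56; 7 higher and 4 lower adjusted over the list alone; adjusted p = 0.429 with an estimated correlation). Of 22 LXR and lipid handling genes 2 were higher, 1 lower and 19 did not pass (median 0.76; 10 higher and 2 lower adjusted over the list alone; adjusted p = 0.336 with an estimated correlation). Of 24 cholesterol synthesis genes 0 passed (median -0.31; 5 lower and 1 higher adjusted over the list alone; adjusted p = 0.472 with an estimated correlation). Of 17 monocyte genes 1 was lower, 0 higher and 16 did not pass (median -0.18; 5 lower adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Single genes higher by this difference were Cd83 (4.04), Mcoln3 (3.35), Fabp4 (2.65), Egr2 (2.39), Atp6v0d2 (2.24), Dio2 (2.23), Pianp (2.14), Fam20c (2.10), Clec7a (2.02) and Mctp1 (2.00). H2-M2 was called too, but some groups are not well above background, so its fitted 2.32 gives no fold. Lower were Mtus1 (-2.74), Raver2 (-2.55), Dmwd (-2.45), Thoc5 (-2.43), Nrxn2 (-2.41), Cd209f (-2.40), Fut7 (-2.13), Sapcd2 (-2.10), Cdkn3 (-2.05), Ube2c (-2.02), Ccnb2 (-1.89) and Rab32 (-1.88).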

How the results depend on the processing

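No alternative was added after the data were seen. With 1 array left out, the group is left with a lone array that is assumed to vary like the other groups; the cause of the changed counts was not tested. Over these fits the counts were 7269 to 8303 for differentiation in control cells without tamoxifen, 5475 to 5700 with it, 5894 to 6147 in flox cells without and 5899 to 7457 with tamoxifen. They were 0 to 0 for tamoxifen in control cells, 224 to 456 in flox cells, 0 to 284 for the difference of these effects, 0 to 326 for the genotypes with tamoxifen and 0 to 156 without. A log2 change of at least 1 left 1889, 1952, 1890 and 2095 genes for differentiation in the same order, 475 for tamoxifen in flox cells, and 499 and 158 for the genotypes with and without tamoxifen, by construction.

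For the other changes the cause was not tested. Without a term for the experiment the counts were 470 for tamoxifen in flox cells, 22 for the difference of effects, and 531 and 2 for the genotypes with and without tamoxifen. Agilent's processed log ratios, and the deposited value table, which holds the same numbers, gave 59, 1239 and 5 for the last 3 of these. Median centring gave 27 for tamoxifen in control cells and 378 for the difference of effects. The shared day 0 RNA as a random block gave 2905 for tamoxifen in flox cells and 824 for the difference. A fit of the compared arrays alone gave 4584 for tamoxifen in flox cells and 0 for the genotypes without tamoxifen; it could not be run for the difference of effects, which needs each group. The day 3 channel alone gave 3140 and 1801 for the genotypes with and without tamoxifen.

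In the day 3 channel alone, some genes had the opposite sign to their ratio. With tamoxifen these included Cd177 (0.37), Ms4a3 (0.62), Camp (0.39), Gfi1 (0.60) and Itgb2l (0.25), and without tamoxifen Clec4f (0.64), Stfa1 (0.71), Cstdc6 (0.12), Orm1 (0.30), Ms4a3 (0.71) and Gfi1 (0.59). The test of S phase genes reversed for tamoxifen in control cells without the first array of those without tamoxifen (median 0.05; 0.05 to 0.36 over the arrays left out) and in flox cells without the second (-0.04; -0.04 to 0.35). That of TREX genes in flox cells reversed without the first (-0.01; -0.17 to -0.01).

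With fry in place of camera, 35 of the list results reported kept their direction and side of the threshold, and 15 lost their call. With an estimated correlation 0 of 121 list calls held. Genes raised by differentiation in control cells (-0.04 under tamoxifen in flox cells), and those raised (0.05) and lowered (-0.02) in flox cells under tamoxifen in control cells, then had adjusted p = 0.582. Adjusted p ranged from 0.00057, 0.00324 and 0.0118 to that value over the alternatives. With median centring the genes lowered in control cells passed in flox cells (0.04, adjusted p = 0.0459; 0.0459 to 0.628 over the alternatives). The 24 genes named for each differentiation comparison passed in each fit with 1 array left out. Median signal over background of 2.39 to 6.09 limits what can be seen in dim genes, and 25.7% to 30.8% of spots have a deposited log ratio of 0.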

Other observations

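The comparison of the day 0 RNA was chosen after results were seen, and the test of the SMAD targets before its result was, but how to read it when the called targets go both ways was settled after. Flox and control cells differed at day 0. Over 4 day 0 samples with 1 residual degree of freedom, limma called 94 of 17996 genes at adjusted p under 0.05, 69 higher and 25 lower in flox cells, with 1532 at an unadjusted p under 0.05, and the experiments correlated across genes, which are not independent replicates, at r = 0.34. Granulocyte genes had a median of 0.97 in flox over control cells at day 0, with 11 of 29 called higher and 0 lower. Mpo stood at 1.93, Ms4a3 at 1.81, Gfi1 at 1.48 and Camp at 1.40, while Elane stood at -0.59, with -0.65 and -0.53 in the experiments. The medians of megakaryocyte genes, 0.70, and of stem and progenitor genes, 0.54, had 0 members called, and that of stromal genes, 0.51, had 1 called higher and 0 lower. The lists were not tested as sets at day 0.

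Id1, Id3 and Smad6, which respond to BMP signals through SMAD proteins, had lower cytoplasmic RNA in flox cells with tamoxifen. Lower output of this pathway was a hypothesis. The median flox tamoxifen effect of 14 other targets was 0.01, with 0.04 and 0.03 in the experiments. The bound set beforehand, a median above -0.2, was met, but the called targets went both ways, Smad7 at -1.68 ± 0.26 (limma adjusted p = 0.0157) and Grem1 at 1.14 ± 0.25 (limma adjusted p = 0.0415), so this median leaves the hypothesis open.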
